A study of Taeniopygia guttata with 46 samples.

How the data were processed

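Posterior telencephalon and testis of adult male zebra finches (Taeniopygia guttata) were profiled by RNA sequencing after 5 h at an air temperature of 27, 35 or 43 °C, which the labels place below, within and above the thermoneutral zone, the range in which a resting animal spends no extra energy on keeping its body temperature. The libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name CASAVA, Trimmomatic 0.36, HISAT2 2.1.0 and featureCounts 1.6.4, without their settings. The genome build and the gene annotation are not given in the sources used here, nor is the strand setting of the counting, so reads of overlapping, antisense or near-identical genes could have been assigned to either gene.

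The authors deposited raw counts per gene, whole numbers without normalization, in 1 table per tissue. Every testis sample has a paired-end column and a single-end column, called runs here, and both held whole numbers. The sources used here do not say whether they are separate runs of the same library, nor whether the paired-end column counts reads or fragments. They were summed to 1 replicate per bird and also analysed separately. In each of 22 birds the deviation of the paired-end column from the mean over birds, on the log scale and over 8391 genes with a mean of at least 200 counts, correlated best with the single-end column of the same bird (r across genes 0.898 to 0.954, against at most 0.469 with another bird). All columns of per-sample values were used, and every row named a gene. Both tables listed the same 18618 Ensembl gene identifiers.

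The files do not pair the identifiers with gene symbols, and the gene table used here (RefSeq names, assembly bTaeGut7.mat) lists no Ensembl identifiers or locus tags, so 0 of the 18618 identifiers could be matched through it. The 34 gene lists (heat shock proteins, cold-inducible RNA-binding proteins, steroidogenesis, cell type markers and others), the set tests on them and the rule for named genes, all fixed before the data were examined, need symbols and were not run. That rule would have named the 10 genes with the smallest p in each direction among the called genes with a symbol, the leading members of each called list, and a fixed set of heat shock, clock, steroid and neural genes. Genes are given by identifier instead, and no function is attached to them. The shares of counts in mitochondrial and haemoglobin genes also need symbols and were not computed.

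Groups came from the labels, with the bird number as replicate. The telencephalon had 8 birds per temperature. The testis had 7 birds at 27 °C, 8 at 35 °C and 7 at 43 °C, and 22 of the 24 birds had both tissues. One testis sample, of bird T142 at 27 °C, carries the tissue characteristic brain while its title and source name say testis. All testis libraries correlated with the mean testis profile at r of at least 0.986 and with the telencephalon at no more than 0.786, and the sample was kept as testis. It was the testis library furthest from the mean of the others of its group (root mean square 0.618 log2 units), closely followed by T155 (0.613). No pair of libraries within a group was a duplicate: the chi-square per degree of freedom between libraries was at least 8.32 in the telencephalon and 29.2 in the testis, where counting noise alone gives about 1.

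Genes were filtered with filterByExpr on group (a minimum count of 10 and a minimum total of 15), which left 13254 genes in the telencephalon and 14149 in the testis. Counts were scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, with robust dispersion estimates, over all 3 temperature groups of a tissue. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The difference between tissues in the response was tested as an interaction over all 6 groups and 46 libraries, on 12523 genes that passed the filter in both tissues. Standard errors of fold changes were derived from the F statistic, and 95% intervals from its degrees of freedom. CPM are TMM-scaled, and log2 CPM used a prior count of 2.

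Further tests were chosen after the data were seen. The shift of the whole profile was the root mean square difference of group means over genes, tested exactly over all splits of the birds of 2 groups. The positions of the groups on the first principal components were tested by exact two-sided permutation. The agreement of the responses of both tissues was tested by exact permutation of temperatures over birds. Groups of tissue-enriched genes (at least 4-fold higher in one tissue and at least 1 CPM there) were tested with camera in limma 3.58.1.

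The fits were tested on simulated counts drawn from the means and library sizes of the real samples. In each simulation 200 genes were changed, all with a mean of at least 10 CPM, and genes varied independently. Recovery at lower levels, or with fewer changed genes, was not tested. In the telencephalon at 43 against 35 °C the test recovered 58% of genes changed by 1.25-fold, 90% at 1.5-fold and 96% at 2-fold, with 9 false calls among 13184 genes tested. In the testis at 43 against 35 °C it recovered 6%, 58% and 96%, with 4 false calls among 14044 genes tested. For the interaction, 81.5% of 200 genes with a 2-fold difference were recovered without a block and 76.0% with the bird as a block, with 13 and 7 false calls among 12523 genes. The simulated libraries were drawn independently, so the tissues of a bird shared no deviation that a block could remove. The simulation therefore cannot show which of these fits serves the real birds better. Its TMM factors were computed over both tissues, those of the real fit within each tissue.

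The bird numbers mark the same animal in both tissues, so they pair the samples. Across 12523 genes, the deviations of a bird's tissues from their group means correlated at a mean r of 0.149, and 19 of 22 birds exceeded 0.1. The interaction was therefore also fitted with the bird as a replicate block in the 22 birds with both tissues. Alternatives set in advance were RLE and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in every library of a group), DESeq2 1.42.0, limma voom with sample quality weights, a test against a 1.2-fold change (glmTreat), fits of the compared groups alone, the bird as a random block in limma, and fits without each library or bird in turn. Surrogate variables (sva 3.50.0), log2 total counts as a covariate, edgeR without robust estimation, DESeq2 with its filter tuned at its default, edgeR on the genes DESeq2 kept, separate testis runs and the removal of single groups of testis samples were added after the data were seen. Splits of the birds were drawn 100 at a time with fixed seeds. Permutation tests of depths used Python 3.11.15 with scipy 1.17.1, and figures matplotlib 3.10.9.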

Results

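Transcript levels were measured in 2 tissues of 24 adult male zebra finches, songbirds whose song circuits and testes both serve courtship and reproduction. Birds were kept for 5 h at 27, 35 or 43 °C. The 46 libraries comprised the posterior telencephalon, a forebrain region, of 8 birds per temperature and the testis of 7, 8 and 7 birds at 27, 35 and 43 °C. Total counts ranged from 10201598 to 16862943 in the telencephalon and from 14232073 to 25440619 in the testis. Mean totals in the telencephalon were 13.3 ± 2.03 M counts at 27 °C (SD, n = 8), 12.2 ± 1.54 M at 35 °C (SD, n = 8) and 12.7 ± 2.19 M at 43 °C (SD, n = 8). In the testis they were 18.9 ± 2.58 M counts at 27 °C (SD, n = 7), 19.5 ± 4.33 M at 35 °C (SD, n = 8) and 19.8 ± 2.20 M at 43 °C (SD, n = 7). The 10 most counted genes held 10.7 to 16.5% of the counts in the telencephalon and 6.54 to 8.08% in the testis. None of 12 exact two-sided permutation tests of totals and of this share between temperatures passed Benjamini-Hochberg correction (all adjusted p = 0.898).

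The biological coefficient of variation between birds was 16.4% in the telencephalon and 29.1% in the testis. In the telencephalon the leading principal components held 8.97% and 8.72% of the variance. On component 2, 7 of 8 libraries at 43 °C lay above 0, against 3 of 8 at 35 °C and 1 of 8 at 27 °C. The difference between 43 and 27 °C (mean 9.90 ± 10.3 SD against -6.43 ± 7.05 SD) had an exact permutation p of 0.00357 and an adjusted p of 0.0429 over 12 tests. The leading components held nearly equal shares of variance and could exchange places. On component 2 the difference was no longer past the threshold in 20 of the 24 sets that left out a bird, in 1 of which, without T155, component 1 separated these groups instead (exact permutation p = 0.00342). The same exchange followed a stricter filter (component 1, exact permutation p = 0.00544, adjusted p = 0.0494). In the testis, 2 of 7 libraries at 43 °C and 6 of 8 at 35 °C lay above 0 on component 1, with an exact permutation p of 0.00979 and an adjusted p of 0.0587. After the stricter filter this was p = 0.00824 (exact permutation, adjusted p = 0.0494). It also passed the threshold in 4 of the 22 sets that left out a testis library (exact permutation p of 0.00566 to 0.0246 over all 22). The testis libraries at 27 °C were spread more widely on component 1 (SD 31.5, against 13.0 at 35 °C and 13.0 at 43 °C). They ran from -48.3 (T142, the sample with the conflicting tissue label) to 37.1 (T155).

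**Figure D1:**
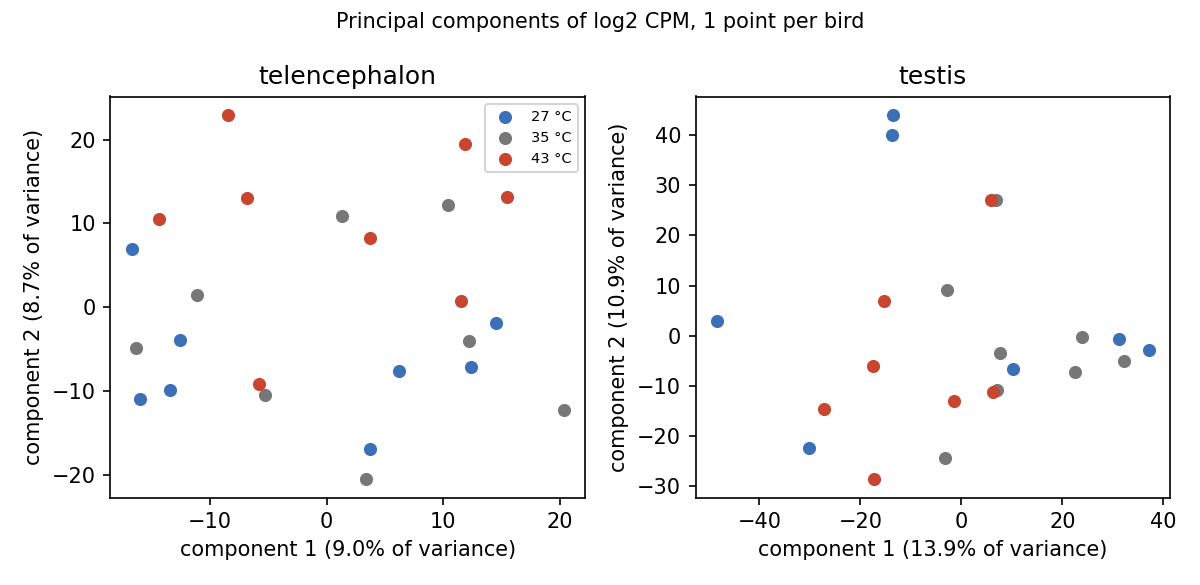
Principal components of log2 CPM in the telencephalon (left) and the testis (right). Each point is the library of a bird, coloured by air temperature, and axes give the share of variance. In the telencephalon 7 of 8 libraries at 43 °C lie above 0 on component 2, against 1 of 8 at 27 °C.

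The comparison of 43 with 35 °C in the telencephalon asks which genes respond to heat above the thermoneutral zone. Of 13254 genes, 1 was called, ENSTGUG00000002065, which rose. Its level was 83.1 ± 6.15 CPM at 43 °C (SD, n = 8) against 65.5 ± 6.36 CPM at 35 °C (SD, n = 8) and 67.1 ± 3.904 CPM at 27 °C (SD, n = 8). The log2 fold change was 0.34 ± 0.059 (SE), a 1.27-fold difference, with an edgeR adjusted p of 0.0472. All 8 birds at 43 °C exceeded the median at 35 °C, which is likely for a gene selected by p in the same comparison. At an unadjusted p under 0.05 there were 1206 genes, 656 higher and 550 lower, or 9.10% of genes where 5% are expected without an effect, and 802 (6.05%) with 3 surrogate variables. DESeq2 called 9 genes, 4 higher and 5 lower, among them the gene called by edgeR, while no gene was called without the filter on low counts or by limma voom with quality weights. Of the 8887 genes with a mean of at least 10 CPM, 96.0% had a 95% interval within a 1.5-fold change in either direction.

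The comparison of 27 with 35 °C in the telencephalon asks about cooling below the thermoneutral zone. No gene was called by edgeR, DESeq2 or limma voom. In edgeR, 448 genes lay at an unadjusted p under 0.05, or 3.38%, with 220 higher and 228 lower. The 95% interval lay within a 1.5-fold change for 96.6% of the genes with at least 10 CPM.

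The widest contrast in the telencephalon was 43 against 27 °C, where 3 genes were called. ENSTGUG00000009960 rose from 72.5 ± 4.75 CPM at 27 °C (SD, n = 8) to 88.2 ± 2.95 CPM at 43 °C (SD, n = 8), a log2 fold change of 0.28 ± 0.048 (SE). ENSTGUG00000010444 rose from 21.5 ± 0.894 CPM (SD, n = 8) to 30.4 ± 4.30 CPM (SD, n = 8), a log2 fold change of 0.50 ± 0.091 (SE). ENSTGUG00000005750 fell from 541 ± 43.2 CPM (SD, n = 8) to 458 ± 16.8 CPM (SD, n = 8), a log2 fold change of -0.24 ± 0.044 (SE). Each had an edgeR adjusted p of 0.0418. All 8 birds at 43 °C lay on the same side of the median at 27 °C, which is likely for genes selected by p in this comparison. The 3 genes were intermediate at 35 °C, with 78.8 ± 5.84, 24.2 ± 4.08 and 504 ± 22.2 CPM (SD, n = 8). A middle position is also likely for genes selected by the difference between the other temperatures. None of the 3 was called against 35 °C. ENSTGUG00000002065 had a log2 fold change of 0.31 ± 0.059 (SE) in this comparison and an edgeR adjusted p of 0.0524. At an unadjusted p under 0.05 there were 1446 genes, 746 higher and 700 lower, or 10.9%. DESeq2 called 64 genes, 41 higher and 23 lower, which included the 3 called by edgeR, and its called genes had a median absolute log2 fold change of 0.28.

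**Figure D2:**
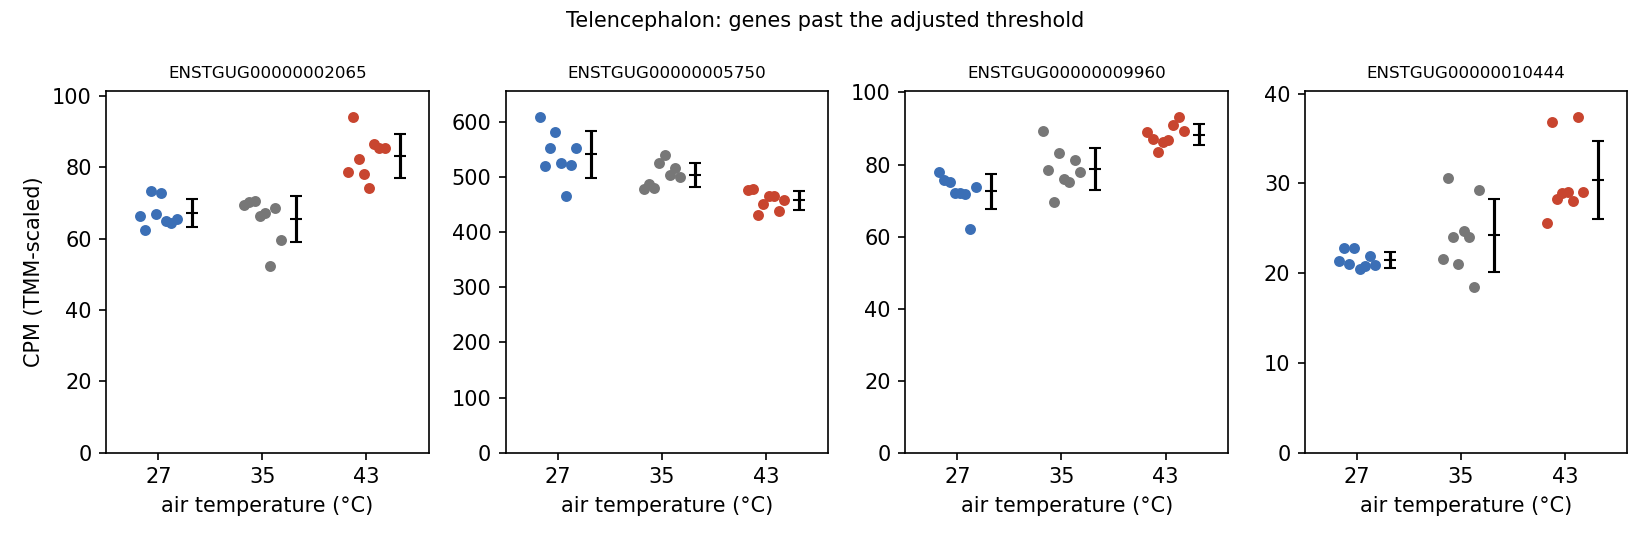
Levels of the 4 genes called in the telencephalon, in TMM-scaled CPM on axes that start at 0, by air temperature. Points are birds (8 per temperature) and the bars beside them are the mean and SD. ENSTGUG00000005750 falls from a mean of 541 CPM at 27 °C to 458 CPM at 43 °C, and the others are higher at 43 °C than at 27 °C.

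These calls lay close to the threshold (edgeR adjusted p of 0.0418 to 0.0472). Most fits that left out 1 bird lost them, while the fold changes moved little. ENSTGUG00000002065 lost its call in 18 of the 24 fits that left out a bird of any temperature, all but those without T145, T155, T139, T140, T135 or T144, with log2 fold changes of 0.30 to 0.36. ENSTGUG00000009960 lost it in 13, all but those without T142, T137, T139, T140, T146, T154, T157, T158, T138, T144 or T156 (log2 fold changes 0.25 to 0.30). ENSTGUG00000010444 lost it in 18, all but those without T137, T139, T154, T157, T158 or T144 (0.45 to 0.53). ENSTGUG00000005750 lost it in 20, all but those without T151, T137, T154 or T144 (-0.26 to -0.21). None of the 4 passed a test against a 1.2-fold change.

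In the testis, no gene was called in any comparison by edgeR or limma voom, over 14149 genes, or by DESeq2, over 17508 genes. Between 43 and 35 °C, 1123 genes lay at an unadjusted p under 0.05 in edgeR, or 7.94%, with 529 higher and 594 lower, and the smallest adjusted p was 0.560. With 1, 2 and 3 surrogate variables the count was 694 (4.90%), 774 (5.47%) and 720 (5.09%), where 5% are expected without an effect. Other alternatives raised it, to 1503 (10.6%) with limma voom with quality weights and 1348 (9.73%) in the fit of the compared groups alone. Without the 3 birds whose paired-end run was the deeper one it was 1366 (9.64%). Between 27 and 35 °C there were 612, or 4.33%, with 348 higher and 264 lower, a count that was 1062 without bird T155. Between 43 and 27 °C there were 873, or 6.17%, with 406 higher and 467 lower. Without T142, whose testis sample carries the conflicting tissue label, there were 1203 (8.45%), and still no gene was called. The larger spread between birds widened the intervals. Of the 8454 genes with at least 10 CPM, 80.5% had a 95% interval within a 1.5-fold change at 43 against 35 °C and 96.7% within a 2-fold change. The genes called in the telencephalon were measured in the testis as well. ENSTGUG00000002065 was at 143.2 ± 15.04 CPM at 43 °C (SD, n = 7) and 164 ± 18.1 CPM at 35 °C (SD, n = 8) there, a log2 fold change of -0.20 ± 0.11 (SE) with an edgeR adjusted p of 0.651. At 43 against 27 °C the testis log2 fold changes of the genes called in that comparison were 0.02 ± 0.13 (SE) for ENSTGUG00000009960, 0.35 ± 0.21 (SE) for ENSTGUG00000010444 and 0.13 ± 0.18 (SE) for ENSTGUG00000005750, with edgeR adjusted p of 0.987, 0.827 and 0.926. Analysed alone, the paired-end run and the single-end run called no gene either.

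Whether the tissues responded differently was tested directly. No gene was called for a difference between tissues at 43 against 35 °C, 27 against 35 °C or 43 against 27 °C in edgeR, over 12523 genes, and none with the bird as a block or in limma voom with the bird as a random block. At an unadjusted p under 0.05 there were 1279, 440 and 913 genes, and 1269, 480 and 851 with the block. Without single birds, up to 4 genes were called at 43 against 35 °C (without T140), and 1 at 27 against 35 °C (without T142 or T155) and at 43 against 27 °C (without T146 or T152). For ENSTGUG00000002065 the testis response at 43 against 35 °C lay below that of the telencephalon by a log2 difference of -0.54 ± 0.12 (SE), with an edgeR adjusted p of 0.141 and 0.322 with the block. The gene was selected by its telencephalon change in this same comparison, so the size of the difference is likely overstated.

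Over the whole profile, the difference between 43 and 27 °C in the telencephalon was 1.14 times the median of all splits of these birds, with an exact permutation p of 0.0157 and an adjusted p of 0.0942 over 6 tests. That between 43 and 35 °C in the testis was 1.15 times the median, with an exact permutation p of 0.0434 and an adjusted p of 0.130. The other 4 had exact permutation p of 0.319 to 0.777. None of the 6 passed the correction. After a stricter filter on low counts the first 2 did, with exact permutation p of 0.00218 (adjusted p = 0.0131) and 0.0101 (adjusted p = 0.0303). Leaving out 1 library at 43 °C also carried each past the correction. For the first this was T156 (exact permutation p = 0.00404, 1 of 16 fits). For the second it was T136 (exact permutation p = 0.0103, 1 of 15 fits).

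The changes from 35 to 43 °C and from 35 to 27 °C share their control birds, which gives correlated fold changes without any effect. For a comparison without effects, the group means were removed and the libraries regrouped at random in 100 draws. Across genes, the correlation was 0.34 in the telencephalon, where these draws gave a mean of 0.49, and 0.51 in the testis, where they gave 0.47. The covariances of 0.00980 and 0.0358 lay within the ranges of the draws, 0.00424 to 0.0223 and 0.0110 to 0.0643. In the telencephalon 95 of 100 draws gave a covariance at least as high, and in the testis 32. With the control birds divided between both changes, the median correlation was -0.11 in the telencephalon and 0.097 in the testis over 70 divisions. Genes are not independent replicates in these correlations.

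**Figure D3:**
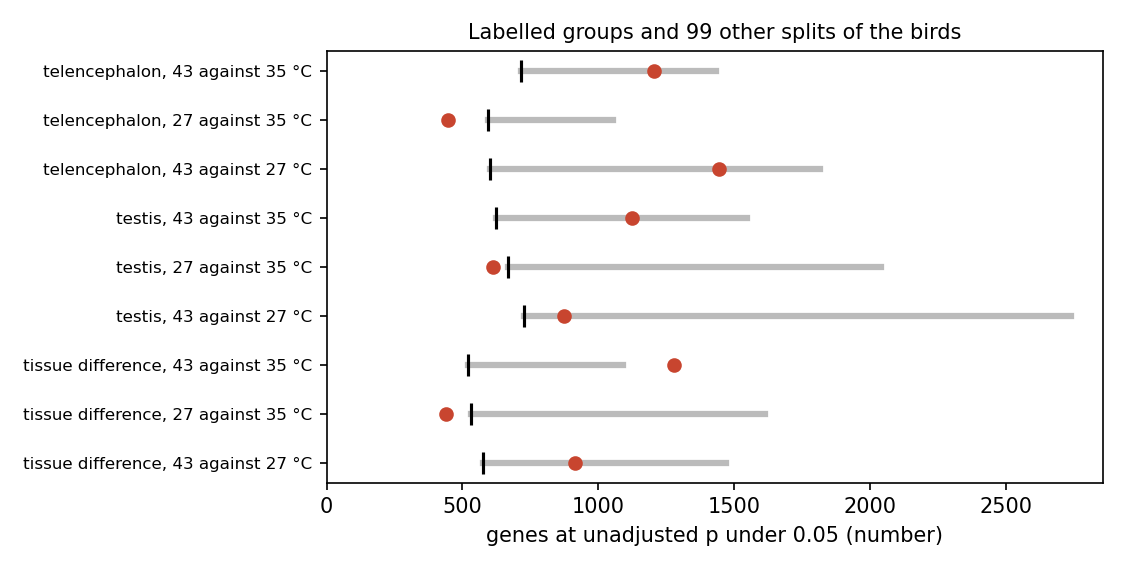
Number of genes at an unadjusted p under 0.05 for each comparison (x axis) in edgeR. Red points are the labelled groups, black marks the median of the 99 other splits of the same birds, and the grey line runs from that median to the highest split. The labelled groups exceed every other drawn split only for the difference between tissues at 43 against 35 °C (1279 genes against at most 1092).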

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

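The splits for unadjusted counts of the difference between tissues, the fits with log2 total counts as a covariate, surrogate variables, edgeR on the genes DESeq2 kept and the fits without 3 birds were chosen after the data were seen. In 5 of 57 groups tested, 1 library stood apart from the others, where chance flags about 1 in 20, or 2.85. In the telencephalon at 27 °C, ENSTGUG00000009960 was at 62.0 CPM in bird T155 and at 71.8 to 77.8 CPM in the other 7. The telencephalon library of bird T153 at 43 °C lay 0.431 log2 units from the mean of the others (root mean square over genes), against 0.352 to 0.386. In the testis, ENSTGUG00000005750 was at 60.0 CPM in bird T157 at 35 °C, against 28.8 to 39.5 CPM, and at 58.8 CPM in bird T152 at 43 °C, against 26.6 to 36.6 CPM. The paired-end run held 61.3% of the testis counts of bird T156 at 43 °C and 41.0 to 41.5% in the other 6 birds. It was also the deeper run in birds T154 (53.6%) and T157 (54.0%) at 35 °C. Without these 3 birds, no testis gene was called in edgeR.

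The response at 43 against 35 °C differed between tissues at an unadjusted p under 0.05 in 1279 genes. Of 100 splits, which moved whole birds and so parted no pair of tissues, 1 gave as many (the labelled split itself). The highest other gave 1092. A share of 1 in 100 is the smallest that 100 splits can give. It was tested after the data were seen and is not corrected for the 3 comparisons here or for those within each tissue. The splits argue against chance for this count taken alone, but do not decide the matter once all comparisons are corrected for. The counts of 440 at 27 against 35 °C and 913 at 43 against 27 °C were reached in 77 and 19 of 100 splits, with highest others of 1614 and 1470. No single gene passed the adjusted threshold in any of the 3, a count of 0 that all 100 splits reach whatever the data, and the highest others called 7, 11 and 7 genes.

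In the telencephalon at 43 against 27 °C, 10.9% of genes lay at an unadjusted p under 0.05. Of 100 splits, the labelled one included, 2 gave as many as 1446 genes (highest other 1815) and 2 gave as many as the 3 called genes (highest other 9), so chance is excluded under the limit of 5 in 100 for this comparison taken alone, but not once the 6 comparisons tested are corrected for. With log2 total counts as a covariate the share was 9.97%, which argues against depth, and without any 1 of the 16 libraries it stayed at 9.01% or more, which argues against a single library. With 1, 2 and 3 surrogate variables it was 11.03%, 9.11% and 7.78%. Air temperature remains a candidate explanation, and differences in dissection or in the cell types of the samples stay open, since marker genes could not be identified.

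DESeq2 called 64 genes in that comparison where edgeR called 3. On the 10110 genes that DESeq2 kept, edgeR called 4, which argues against the filter as the source of the difference. DESeq2 reached 64 genes in 2 of 100 splits (highest other 82), but it also called genes in 56 of the 99 other splits, where edgeR did so in 8. At 43 against 35 °C its 9 genes were matched by 16 of 100 splits (highest other 86), so chance is not excluded for them. The individual genes of the longer lists may therefore include calls that the grouping of birds alone gives.

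For the remaining counts above 0 chance is not excluded, and each number of splits includes the labelled one. The gene called by edgeR at 43 against 35 °C in the telencephalon was matched in 11 of 100 splits (highest other 1), and the 1206 genes at an unadjusted p under 0.05 in 5 (highest other 1435). At 27 against 35 °C, the 448 genes were matched in 82 (highest other 1053). Counts of 0 are reached by all 100 splits whatever the data, so for them the splits decide nothing. The highest other split called 1 gene at 27 against 35 °C in the telencephalon, and in the testis the highest others called 2, 9 and 703 genes at 43 against 35, 27 against 35 and 43 against 27 °C. The testis counts of 1123, 612 and 873 genes at an unadjusted p under 0.05 were reached in 6, 58 and 38 splits, with highest others of 1548, 2039 and 2741. The 703 calls came from 1 of the 9 other splits that called any gene at 43 against 27 °C. A split with that many calls points to some structure among the testis samples. The birds at 27 °C were spread widely on testis component 1 (SD 31.5), but whether this gave the calls was not tested.

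Telencephalon and testis of the same bird deviated from their group means together, with a mean correlation across 12523 genes of 0.149 (0.0544 to 0.244). Between different birds of a group it was -0.024. Centring on the group means makes that value slightly negative by itself, so it is no independent baseline. Among the birds of the same temperature, 20 of 22 telencephalon libraries matched their own bird best. Random pairing within a temperature gave a permutation p of 1e-04 for the mean same-bird correlation, the smallest that 10000 permutations can give. With log2 totals regressed out the mean same-bird correlation was 0.144, which argues against depth. Genes enriched in one tissue tracked less between tissues than shared genes of like expression (difference of median same-gene correlations -0.077, and -0.087 to -0.068 without each bird in turn). This argues against RNA carried between libraries as the main source. A small carried amount, or one that varied between birds, is not excluded, since a median over all enriched genes could miss it. Without the 5% of genes that tracked best in 11 birds, the mean in the other 11 was 0.122 (0.103 to 0.140 over 20 halvings), which argues against a small set of genes as the whole source. Differences between birds, such as genotype or condition, and a shared day or batch stay open, and no biological explanation was tested.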

How the results depend on the processing

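Surrogate variables, the depth covariate, edgeR on the genes DESeq2 kept, edgeR without robust estimation, DESeq2 with its filter tuned at 0.1, the subsets of testis runs and birds, and all alternatives for the whole-profile shift and the principal components were chosen after the data were seen; the others were fixed before. The gene list tests (estimated correlation, fry, RLE, left-out libraries) and those of symbol-named genes were not run, because no identifier had a symbol.

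No testis count and no count at 27 against 35 °C in the telencephalon left 0 under any alternative, including 0 to 0 genes without each library. In the telencephalon at 43 against 35 °C, the 1 call went to 0 with no filter, glmTreat at 1.2-fold, limma voom with quality weights, only the compared groups (fewer samples), log2 total counts as a covariate, and 1, 2 or 3 surrogate variables. It went to 9 with DESeq2, 8 with its filter tuned at 0.1 and 3 in edgeR on the genes DESeq2 kept (fewer genes tested). Without single libraries it ranged from 0 to 3, differing from 1 in 23 of 24 fits. At 43 against 27 °C the 3 calls went to 6 with no filter, 5 with the stricter filter, 0 with glmTreat, 5 with limma voom, 64 with DESeq2, 51 with its filter tuned at 0.1, and 1, 0 and 0 with 1, 2 and 3 surrogate variables. Without single libraries they ranged from 0 (12 fits, such as without T143 at 27 °C) to 10 (without T144 at 43 °C). The cause was not tested except where given. RLE and upper-quartile scaling changed no count by over 1.5 times.

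For the difference between tissues, the bird as a replicate block (0, 0 and 0 calls) and as a random replicate block changed no call. Without single birds the counts ranged from 0 to 4 at 43 against 35 °C (4 without T140, 3 without T139 or T152, 2 without T154, 1 without T155, T137 or T147), from 0 to 1 at 27 against 35 °C (1 without T142 or T155) and from 0 to 1 at 43 against 27 °C (1 without T146 or T152).

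The whole-profile shift passed the correction after the stricter filter in the telencephalon at 43 against 27 °C (exact p = 0.00218, adjusted p = 0.0131) and in the testis at 43 against 35 °C (exact p = 0.0101, adjusted p = 0.0303). It also passed in 1 leave-one-out fit of each, without T156 in the telencephalon and without T136 in the testis. The cause was not tested. Without single libraries its exact permutation p ranged from 0.00404 to 0.0462 and from 0.0103 to 0.136 in these, from 0.135 to 0.669 and from 0.605 to 0.896 in the telencephalon at 43 and 27 against 35 °C, and from 0.142 to 0.783 and from 0.254 to 0.702 in the testis at 27 against 35 and 43 against 27 °C. The share of the 20 most counted genes, in place of 10, gave no p under 0.05. No called gene changed direction.

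The number of genes at an unadjusted p under 0.05 moved by over 1.5 times with surrogate variables at 43 against 35 °C, from 1206 to 802 (6.05%) in the telencephalon with 3, and from 1123 to 694 (4.90%) with 1 and 720 (5.09%) with 3 in the testis; the cause was not tested. It also fell to 787 of 7160 genes (10.99%) in the telencephalon at 43 against 35 °C on the genes DESeq2 kept (fewer genes tested), and in all 6 comparisons with glmTreat. In the testis at 27 against 35 °C it went from 612 to 1062 without T155.

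The testis libraries were deeper, and birds differed more there (coefficient of variation 29.1% against 16.4%). Among genes with a mean of at least 10 CPM, the simulated test recovered 6% of the smallest changes at 43 against 35 °C there and 58% in the telencephalon.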

Other observations

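The gene groups and tests in this part were chosen after the data were seen. Genes were grouped by the tissue in which they were at least 4-fold higher, over all birds. In the telencephalon at 43 against 35 °C, 245 of 2634 telencephalon-enriched genes were higher and 94 lower at an unadjusted p under 0.05, with a median log2 fold change of 0.021. At 43 against 27 °C, 259 were higher and 115 lower. Neither group passed the correction over 18 camera tests (adjusted p = 0.115 and 0.106 with a preset correlation, adjusted p = 0.284 and 0.271 with an estimated correlation). Of 1589 testis-enriched genes measured in the telencephalon, 50 were higher and 94 lower at 43 against 27 °C (adjusted p = 0.362, and adjusted p = 0.313 with an estimated correlation). In the testis at 43 against 27 °C, 125 of 2546 testis-enriched genes were higher and 66 lower, with a median log2 fold change of 0.040 (adjusted p = 0.0668, and adjusted p = 0.313 with an estimated correlation). None of the 18 tests passed with either correlation, and the smallest adjusted p with an estimated correlation was 0.0990.

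The responses of both tissues to 43 against 35 °C correlated across 12523 genes at 0.040, below the median of 0.14 that all splits of these 15 birds gave (exact permutation p = 0.0385, two-sided, adjusted p = 0.116 over 3 comparisons). At 27 against 35 °C the correlation was 0.16, against a median of 0.15 (exact permutation p = 0.802), and at 43 against 27 °C 0.11, against 0.16 (exact permutation p = 0.294). None passed the correction. Genes at an unadjusted p under 0.05 and higher at 43 than at 35 °C in both tissues numbered 27, where independent lists would share 23.6, and those lower in both numbered 17, where they would share 21.9. At 27 against 35 °C the lists shared 18 higher and 12 lower genes, where independent lists would share 5.16 and 3.71. At 43 against 27 °C they shared 28 higher and 51 lower genes, where independent lists would share 19.6 and 22.1. The overlaps were not tested by permutation, and both lists come from the same birds, whose tissues deviate together, so independent lists are not what is expected without an effect.

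ENSTGUG00000012827, singled out after its values were seen, had the smallest unadjusted p in the testis at 43 against 27 °C. It was at 15.5 ± 4.19 CPM at 43 °C (SD, n = 7), 27.9 ± 10.001 CPM at 35 °C (SD, n = 8) and 31.8 ± 6.92 CPM at 27 °C (SD, n = 7), a log2 fold change of -1.03 ± 0.22 (SE) at 43 against 27 °C, and its edgeR adjusted p was 0.728. In the telencephalon it was at 10.2 ± 1.30, 15.9 ± 5.38 and 11.1 ± 1.85 CPM at 43, 35 and 27 °C (SD, n = 8), with an edgeR adjusted p of 0.371 at 43 against 35 °C.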
